A study of Mus musculus and Homo sapiens with 27 samples.

How the data were processed

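RNA sequencing of cultured medulloblastoma cells was analysed in 27 libraries that fall into 9 groups of 3, and the labels give every library its group and replicate number. Mouse cohort 1 holds cells from Ptch1-deficient mice kept with phosphate-buffered saline (PBS) or with triiodothyronine (T3, the active thyroid hormone, 200 nM). Mouse cohort 2 holds cells of the same genotype kept with PBS, with T3 (200 nM, 48 h) or with GSK126, an inhibitor of the histone methyltransferase EZH2. The labels give the GSK126 dose as 1 mM, and that unit could not be checked. The human libraries come from a pair of patient-derived orthotopic xenograft (PDOX) lines, one of the SHH subgroup and one of Group 3, each kept with PBS or T3. Per the labels' protocols, tumours were dissociated with papain and the libraries were strand-specific. For cohort 2 and the PDOX lines a Percoll gradient and polyA capture were also named. Nothing in the labels says whether the replicates of a group come from separate animals, tumours or cultures, so every p-value measures the spread between these libraries, which may be technical in part. Cohort 1 did hold more than 1 animal, since the libraries numbered 3 held the female transcript Xist at 869 (PBS) and 1060 CPM (T3), and the other 4 held at most 0.523 CPM.

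For mouse cohort 1 the authors deposited whole read counts per gene together with FPKM values. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.1.4, featureCounts 2.0.1 and fastp were used with the mm10 genome. For cohort 2 and for the PDOX lines the authors deposited estimated counts per gene, which are not whole numbers, and the submitters' processing notes name Salmon with mm39 and hg38. Whether the counting used the strand is not stated, so overlapping and antisense genes, and members of families with near-identical copies, are uncertain. Gene symbols were used as the files give them. Mouse gene types and positions were looked up by symbol in GENCODE M21, which is of the GRCm38 build. Mouse and human genes were matched by symbol in upper case, which only approximates orthology.

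From these values the following was computed with R 4.3.3. Estimated counts were rounded to whole numbers. Each comparison was fitted with the quasi-likelihood test of edgeR 4.0.16 (robust fit) after filterByExpr and TMM normalisation, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Cohort 1, cohort 2 (3 groups in a joint fit), the SHH line and the Group 3 line were fitted separately. The difference of the T3 effect between the PDOX lines was the interaction term of a joint fit. A log2 fold change is the first-named group over the second, SE is its standard error, and levels are normalised CPM given as the mean with the SD of 3 libraries. CPM values of the 3 tables are not on a common scale. The 7 comparisons, their tests, the gene lists and the alternatives were written down before the data were examined.

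The 24 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Lists with fewer than 5 tested members were not tested. Camera with an estimated correlation and fry were alternatives. Of lists called, only cell cycle genes in the difference between PDOX lines held with the former. This test ignored replicate pairs, so its p may be high. In every list called, median, mean and test had the same sign. Members past the threshold are counted over all genes tested and adjusted over the list alone.

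The genes named were set by a rule. It took 10 key genes (Neurod1, Rbfox3, Gli1, Atoh1, Mki67, Hr, Klf9, Thra, Thrb and Ezh2) whether called or not. It added the 6 genes with the largest positive and the 6 with the largest negative change among those called with a mean log2 CPM of at least 3 and no overlap between groups (4 and 4 for the interaction). Unnamed, predicted, mitochondrial, XIST, Y-linked and pseudogene entries were left out of these. It then added up to 4 called members of each list past the threshold and up to 2 of the other lists. Genes named outside this rule are said to be so where they appear. Some genes that the rule names are not reported.

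Replicate numbers could mark pairs, so the correlation of deviations from the group means was computed for libraries with the same number. In cohort 1 it was 0.608, 0.655 and 0.772, and between T3 and GSK126 in cohort 2 it was 0.284, 0.624 and 0.502, so the numbers were taken as pairs there by a limit set in advance. In the other comparisons at least 1 pair was below that limit. The pairing comes from these values and not from the labels. The fits without the block stay the reported ones. In these paired comparisons the blocked value is given where it changes a call, and in the others it is given as counts of calls in the closing part on processing.

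Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, the replicate number as a block, a test against a 1.5-fold change (glmTreat), each library left out in turn, limma on log2 FPKM for cohort 1, fits of the compared groups alone, and both PDOX lines in a joint fit. Alternatives added after seeing the data left out libraries that stood apart, kept protein-coding genes alone, or fitted T3 and GSK126 libraries alone with the block. Fits were tested on data simulated from each table's means and spread with few changes. Of 67 genes changed 2-fold, 37.3% were recovered in cohort 1, 47.8% (T3) and 43.3% (GSK126) in cohort 2 and 49.3% for T3 against GSK126. The SHH line gave 91%, the Group 3 line 85.1% and the interaction 74.6%. False calls were 3.09% to 10%. In mice 33.4% to 36.3% were called against PBS, so recovery may differ. Depth and spread set precision. Cohort 1 libraries held 39.1 to 51.9 M counts, cohort 2 libraries 14.6 to 17.0 M and PDOX libraries 15.4 to 16.9 M, and the common dispersion was 0.0884 in cohort 1, 0.0733 in cohort 2, 0.00166 in the SHH line and 0.0141 in the Group 3 line. Variants and reads of mouse origin in the PDOX libraries were not analysed here.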

Results

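Gene expression was measured by RNA sequencing in medulloblastoma cells taken from Ptch1-deficient mice and in cells of a pair of human PDOX lines, one of the SHH subgroup and one of Group 3. There were 27 libraries in 9 groups of 3. Cohort 1 was kept with PBS (40.2 to 46.1 M counts per library) or T3 (39.1 to 51.9 M). Cohort 2 was kept with PBS (14.6 to 15.5 M), T3 (16.3 to 17.0 M) or GSK126 (15.6 to 16.7 M). The SHH line was kept with PBS (16.84 to 16.88 M) or T3 (16.8 to 16.85 M), and the Group 3 line with PBS (16.0 to 16.2 M) or T3 (15.4 to 16.1 M). The main mouse genes lie, in GRCm38 with GENCODE M21 and as protein-coding genes, on chromosome 2 from 79452521 to 79456751 (Neurod1), 11 from 118489762 to 118911597 (Rbfox3) and 10 from 127329882 to 127341974 (Gli1). Hr lies on chromosome 14 from 70552212 to 70573548 and Klf9 on 19 from 23141226 to 23168134.

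The question put to cohort 1 was what T3 does to genes of neuronal differentiation and to targets of the SHH pathway. Genes of neurons were higher with T3 and SHH targets were lower. Neurod1, a transcription factor of differentiating granule neurons, was at 753 ± 86.2 CPM (SD, n = 3) with T3 and 335 ± 118 with PBS, a log2 fold change of 1.17 (SE 0.267, adjusted p = 0.0192). Rbfox3, which encodes the neuronal nuclear protein NeuN, rose by 1.07 (SE 0.192, adjusted p = 0.00898), to 334 ± 43.8 CPM from 159 ± 38. Gli1, the transcription factor that carries and reports SHH signalling, changed by -1.79 (SE 0.242, adjusted p = 0.00423), to 46.9 ± 12.3 CPM from 162 ± 36. Of 16012 genes tested, 2458 rose and 2890 fell, and in 51.6% the libraries of the groups did not overlap, where chance gives 10%. With the replicate number as a block the number called was 8585 in place of 5348. Without T3 2 it was 2767 and without T3 1 it was 3322, and Neurod1 missed the threshold without PBS 2 (adjusted p = 0.0615) or T3 2 (0.0527), within a range of 0.00011 to 0.107 over its alternatives.

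**Figure D1:**
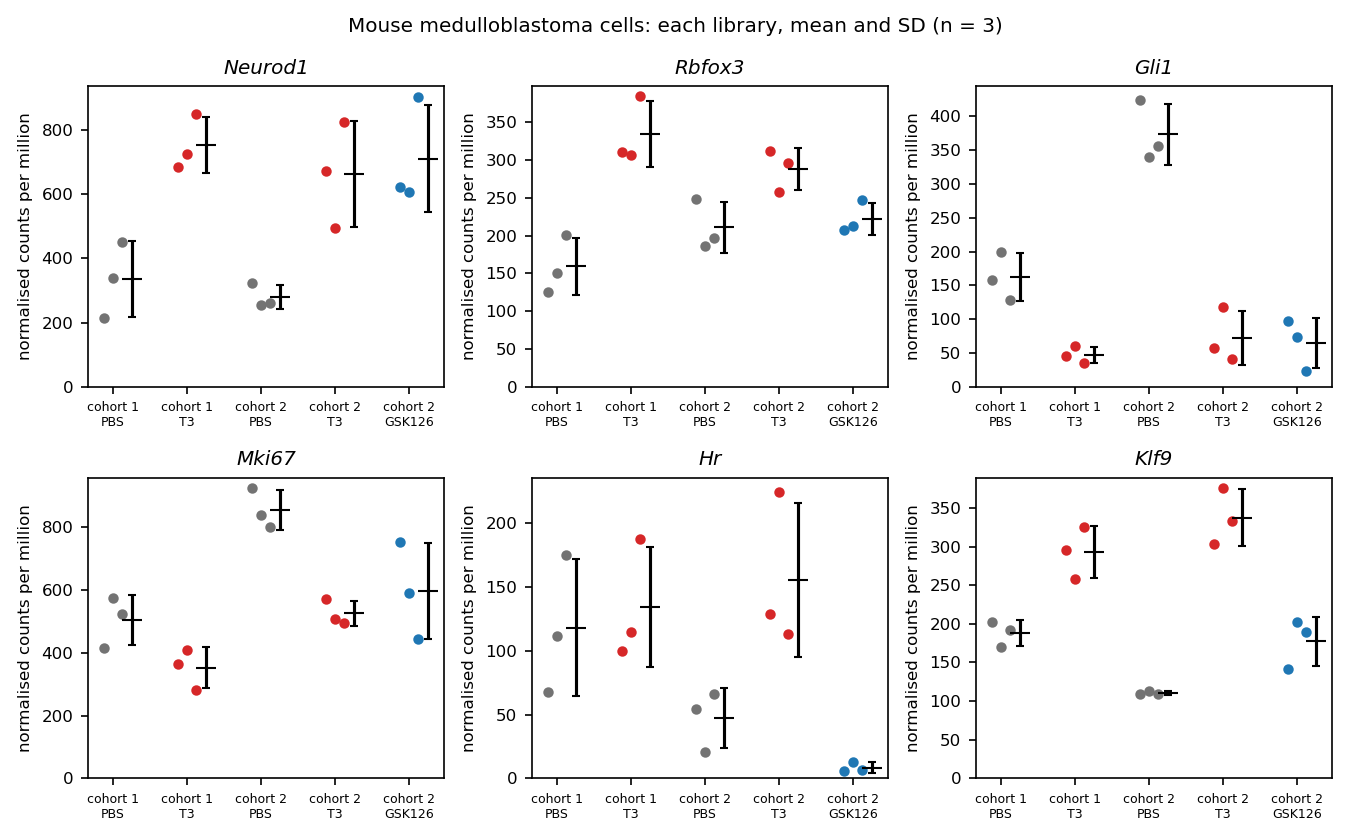
Normalised CPM of 6 genes in each mouse library, with points for libraries and lines for group means, and the cohorts normalised separately. Neurod1 was higher and Gli1 lower with T3 than with PBS in every library of both cohorts, and Hr with GSK126 lay below PBS.

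Neuronal genes rose together with T3 in cohort 1. Of 29 pan-neuronal and synaptic vesicle genes 23 rose and none fell (26 rose adjusted over the list alone), among them Snap25, a protein of vesicle fusion (1.96, SE 0.111), Syt1, a calcium sensor of release (1.76), Syp (1.59) and Rbfox1 (1.42). The list's median was 1.09, with adjusted p = 1.1e-10 by camera and adjusted p = 0.491 with an estimated correlation. Of 22 granule neuron differentiation genes 9 rose (11 rose and 1 fell adjusted over the list alone), with Neurod2 (1.69), the adhesion protein gene Cntn1 (2.58), Fat2 (2.61) and the synapse organiser Cbln1 (1.20). Its median was 1.08 (adjusted p = 6.31e-05, and adjusted p = 0.353 with an estimated correlation). Of 30 glutamate and GABA receptor genes 17 rose and 1 fell, also adjusted over the list alone, with Gabra2 (3.99), Grm4 (2.35) and Grm7 (1.59). Of 36 voltage-gated ion channel genes 18 rose and 3 fell (21 and 4 adjusted over the list alone), with Cacna2d3 (2.64), Scn2a (1.35), Cacna1c (1.26) and Scn3b (1.25). Of 54 axon guidance genes 15 rose and 4 fell, the same counts adjusted over the list alone, with the netrin receptors Unc5b (1.88) and Unc5c (1.88), Plxnd1 (1.06) and Robo2 (1.02). Camera gave adjusted p = 9.1e-06 for receptors, 1.63e-05 for channels and 0.00204 for axon guidance, and each had adjusted p = 0.491 with an estimated correlation.

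SHH pathway genes, ribosome biogenesis genes and stress genes fell with T3 in cohort 1. Of 18 SHH pathway genes 8 fell and none rose, the same adjusted over the list alone (median -0.75, adjusted p = 0.000641, and adjusted p = 0.353 with an estimated correlation). Besides Gli1 these included Hhip, a secreted inhibitor of the pathway (-3.19, SE 0.23), and the receptor Ptch1 (-1.01). The labels give the cells as Ptch1-deficient, and Ptch1 counts were at 208 ± 17.9 CPM with T3 and 418 ± 51.6 with PBS. Of 28 MYC target and ribosome biogenesis genes 26 fell, also adjusted over the list alone, with Rrp12 (-1.59), the RNA helicase gene Ddx21 (-1.37), Wdr43 (-1.31) and Dkc1 (-1.27). The list's median was -1.03 (adjusted p = 2.02e-13, and adjusted p = 0.353 with an estimated correlation). Of 26 unfolded protein, heat shock and oxidative stress genes 21 fell, also adjusted over the list alone, with the small chaperone gene Hspb1 (-5.05), Atf4 (-1.27), Srxn1 (-0.97) and Hsph1 (-0.78). Its median was -0.91 (adjusted p = 1.26e-06, and adjusted p = 0.491 with an estimated correlation). Of 46 cell cycle genes 11 fell and 1 rose (9 and 1 adjusted over the list alone), with Mcm6 of the replicative helicase (-1.04), Cdc20 (-0.74) and Cdc25a (-0.47) lower and E2f2 (0.52) higher. Its median was -0.31 (adjusted p = 0.00313, and adjusted p = 0.809 with an estimated correlation), and fry missed it without the block (0.17) and with it (0.229), in a range of 0.000183 to 0.809. Mcm6 missed the threshold without PBS 2 (adjusted p = 0.0501), T3 2 (0.0611) or T3 3 (0.0505), and Cdc20 without both libraries numbered 3 (0.0547). Over their alternatives the adjusted p of Mcm6 ranged from 0.000207 to 0.121 and that of Cdc20 from 0.000438 to 0.29.

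Genes of the thyroid hormone response were less uniform in cohort 1. Klf9, a direct T3 target in many tissues, rose by 0.64 (SE 0.121, adjusted p = 0.0103), while Hr, a nuclear corepressor gene that T3 commonly induces, was at 135 ± 47.2 CPM with T3 and 118 ± 53.8 with PBS (0.19, SE 0.388, adjusted p = 0.736). The receptor genes Thra (1.35, adjusted p = 0.00853) and Thrb (3.35, adjusted p = 0.00434) rose. Mki67, a marker of dividing cells, Ezh2 and Atoh1, a progenitor transcription factor, missed the threshold at -0.52 (adjusted p = 0.0697), -0.27 (0.321) and -0.31 (0.587). With the replicate block all 3 passed it, at adjusted p = 0.0126, 0.0299 and 0.032, the low ends of ranges over their alternatives that reach 0.918, 1 and 1. Of 19 thyroid hormone responsive genes 2 rose and 3 fell, and of 17 genes of thyroid hormone receptors, transport and metabolism 3 rose and 4 fell, with no other counts adjusted over the list alone (camera adjusted p = 0.789 for each). The monocarboxylate transporter gene Slc16a3 (2.03) rose and Ier5l (-0.80) fell within the first of these lists.

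Among genes eligible by the naming rule, the largest falls in cohort 1 were in Iigp1 (-4.98), Ifit3b (-4.95), Rsad2 (-4.89, SE 0.729), Ifit3 (-4.61), Ifi44 (-4.59) and the chemokine gene Cxcl10 (-4.46), all of which interferon induces. The largest rises were in Atp2b3, a calcium pump of the plasma membrane (5.16, SE 0.622), Car10 (4.99), Il16 (4.38), the neural adhesion gene Opcml (4.31), Gabra2 and Tgfbi (3.82). Iigp1 and Ifit3 missed the threshold without T3 2 (adjusted p = 0.0535 and 0.0532). Tgfbi missed it when any library but T3 3 was left out, at adjusted p = 0.081 without PBS 1, 0.0592 without PBS 2, 0.059 without PBS 3, 0.0567 without T3 1 and 0.0714 without T3 2. The ranges over the alternatives were 8.03e-07 to 0.0535 for Iigp1, 9.16e-07 to 0.0532 for Ifit3 and 0.000593 to 0.0883 for Tgfbi. Beyond the naming rule, the libraries PBS 3 and T3 3 held Xist at 869 and 1060 CPM and the other 4 at most 0.523, with Y-linked genes at 148 to 196 CPM, so the pair numbered 3 came from female mice and the others from males.

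Markers of other cell types also moved in cohort 1, beside the neuronal and SHH lists. Of 16 astrocyte and glial progenitor markers 8 fell and 1 rose, also adjusted over the list alone (median -1.19, adjusted p = 0.0634), with the glutamate transporter gene Slc1a3 (-1.39) and Gdf10 (-2.56). Of 13 endothelial and mural markers 5 fell and 1 rose, also adjusted over the list alone (median -1.10, adjusted p = 0.0653), with Flt1 (-3.10) and Rgs5 (-2.87) at under 2 CPM. Camera called the astrocyte list without T3 1 (adjusted p = 0.0271) or T3 2 (0.0412), and the endothelial list without PBS 2 (0.0345), PBS 3 (0.0274), T3 1 (0.0464) or T3 2 (0.00581), in ranges over the alternatives of 3.95e-05 to 0.491 and 0.000175 to 0.491. Of 17 microglia and macrophage markers 1 rose, none adjusted over the list alone (median 0.82, adjusted p = 0.496, and 0.00484 without T3 3, in a range up to 0.966). Of 8 GABAergic neuron markers 3 fell and 1 rose, also adjusted over the list alone, with Gad1 (-3.69) and Sst (-3.25; adjusted p = 0.407). Of 15 oligodendrocyte lineage markers 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.326), with Gpr17 (2.08). Of 14 fibroblast and meningeal markers 2 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.739), with Acta2 (-4.40) and Fn1 (-1.65), and of 3 erythroid markers tested none was called.

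The remaining lists were not called in cohort 1. Of 17 granule neuron progenitor genes 2 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.789), with the progenitor factor genes Sox9 (-1.37) and Hes1 (-2.69). Of 13 PRC2 subunit genes, which encode the complex around EZH2, 1 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.407), with Ezh1 (0.87). Of 23 Polycomb-repressed developmental regulator genes 1 rose and 1 fell, none adjusted over the list alone (adjusted p = 0.821). Of 24 p53 target genes 4 rose and 2 fell, also adjusted over the list alone, with Sesn1 (0.98) and Gadd45a (0.91). That list's median was -0.04 and its mean 0.05, and the test pointed up (adjusted p = 0.666). Of 25 cholesterol synthesis genes 1 rose and 1 fell (1 and none adjusted over the list alone), with a median of -0.05, a mean of 0.01 and a test pointing down (adjusted p = 0.789, and 0.0495 without T3 3, in a range up to 0.94). Of 12 photoreceptor and Group 3 markers 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.789).

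Cohort 2 put the same question about T3 to separately made libraries. Neurod1 rose by 1.25 (SE 0.219, adjusted p = 0.00316), to 663 ± 164 CPM with T3 from 280 ± 37 with PBS (n = 3), and Gli1 changed by -2.38 (SE 0.533, adjusted p = 0.0104), to 72 ± 40.3 CPM from 374 ± 44.8. Klf9 rose by 1.61 (SE 0.143, adjusted p = 0.000239) and Hr by 1.72 (SE 0.474, adjusted p = 0.0224), the latter to 156 ± 60.6 CPM from 47.3 ± 23.6. Thra (1.06, adjusted p = 0.00183) and Thrb (1.83, adjusted p = 0.009) rose, Mki67 changed by -0.70 (adjusted p = 0.0142), and Rbfox3 rose by 0.45 (adjusted p = 0.0283). Ezh2 (0.33, adjusted p = 0.192) and Atoh1 (0.32, adjusted p = 0.493) missed the threshold. Of 15753 genes tested, 2879 rose and 2730 fell, and in 51.4% the groups did not overlap (chance, 10%). Without T3 3 the number called was 3734 in place of 5609. Hr missed the threshold without T3 2 (adjusted p = 0.0651), Mki67 without T3 3 (0.063), and Rbfox3 without T3 1 (0.0756), T3 3 (0.071), PBS 2 (0.0799) or PBS 3 (0.0813), where the ranges over the alternatives were 0.000278 to 0.0873, 0.00101 to 0.382 and 0.0111 to 1.

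Neuronal, cholesterol and p53 target genes rose with T3 in cohort 2. Of 28 pan-neuronal and synaptic vesicle genes 20 rose and none fell, also adjusted over the list alone, with Syt1 (2.40), Syn2 (2.34, SE 0.149), Snap25 (1.70) and the growth cone gene Stmn2 (1.3). Of 25 cholesterol synthesis genes 21 rose (23 adjusted over the list alone), with Hmgcs1, an early enzyme of the pathway (2.56, SE 0.371), Nsdhl (1.79), Sqle (1.58) and Sc5d (1.26). Of 24 p53 target genes 14 rose and 2 fell, also adjusted over the list alone, with Trp53inp1 (2.22), Ccng1 (1.77) and Zmat3 (1.08) higher and Btg2 (-1.98) lower. The medians were 1.10, 1.22 and 0.70, with camera adjusted p = 5.56e-08, 3.45e-08 and 0.00148, and each had adjusted p = 0.504 with an estimated correlation. The largest rises among eligible genes were in Pcp4 (4.23, SE 0.561), Tcaf2 (3.91), Diras2 (3.89), Cemip (3.57), H2-Q7 (3.19) and the adenylate cyclase gene Adcy1 (3.13).

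SHH pathway, progenitor and MYC target genes fell with T3 in cohort 2. Of 18 SHH pathway genes 7 fell and none rose, also adjusted over the list alone, with Hhip (-2.12), Ptch1 (-1.56) and Gli2 (-1.39). The median was -0.82 (adjusted p = 0.0158, and adjusted p = 0.504 with an estimated correlation). Of 19 granule neuron progenitor genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Mfap4 (-3.90), Id1, an inhibitor of differentiation (-2.29), and Barhl1 (-0.61, to 706 ± 34.6 CPM from 1076 ± 126). The median was -0.61 (adjusted p = 0.0423, and adjusted p = 0.504 with an estimated correlation), and the call was lost without T3 1 (0.0708), T3 3 (0.073), PBS 1 (0.0694) or PBS 2 (0.0533), in a range of 1.8e-07 to 0.504. Of 28 MYC target and ribosome biogenesis genes 14 fell and 3 rose, also adjusted over the list alone, with Myc itself (-1.90), Ppan (-1.47), Utp20 (-0.83) and Mybbp1a (-0.79). That median was -0.44 (adjusted p = 0.00181, and adjusted p = 0.566 with an estimated correlation).

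The largest falls among eligible genes in cohort 2 included immediate-early genes, with Fos at 3.69 ± 2.29 CPM with T3 against 1674 ± 640.4 with PBS (-8.82, SE 0.859) and Egr1 at 6.25 ± 3.4 against 1332 ± 558.9 (-7.73, SE 0.695). Fosb, Klf4, the histone gene H2ac24 and the heat shock gene Hspa1b were the other 4 of these 6. The PBS libraries of this cohort stood apart from the T3 and GSK126 libraries in further ways. Entries typed as pseudogenes took 1.31% of counts with PBS (SD 0.121), 0.653% with T3 (SD 0.113) and 0.602% with GSK126 (SD 0.0252), and histone genes took 0.191%, 0.0972% and 0.101%. Of the non-zero values, 39.4% to 41.1% were not whole numbers in PBS libraries, and 55.3% to 64.1% in treated ones. Beyond the naming rule, the library PBS 2 held the X-inactivation transcript Xist at 938 CPM, and T3 2 and GSK126 2 held 0.236 and 0.248 CPM with Y-linked genes at 191 and 196 CPM, so PBS 2 came from another animal than these. In an alternative chosen after the data were seen, protein-coding genes alone, without histone, ribosomal protein and mitochondrial genes, gave 4634 calls for T3 and 4791 for GSK126.

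**Figure D2:**
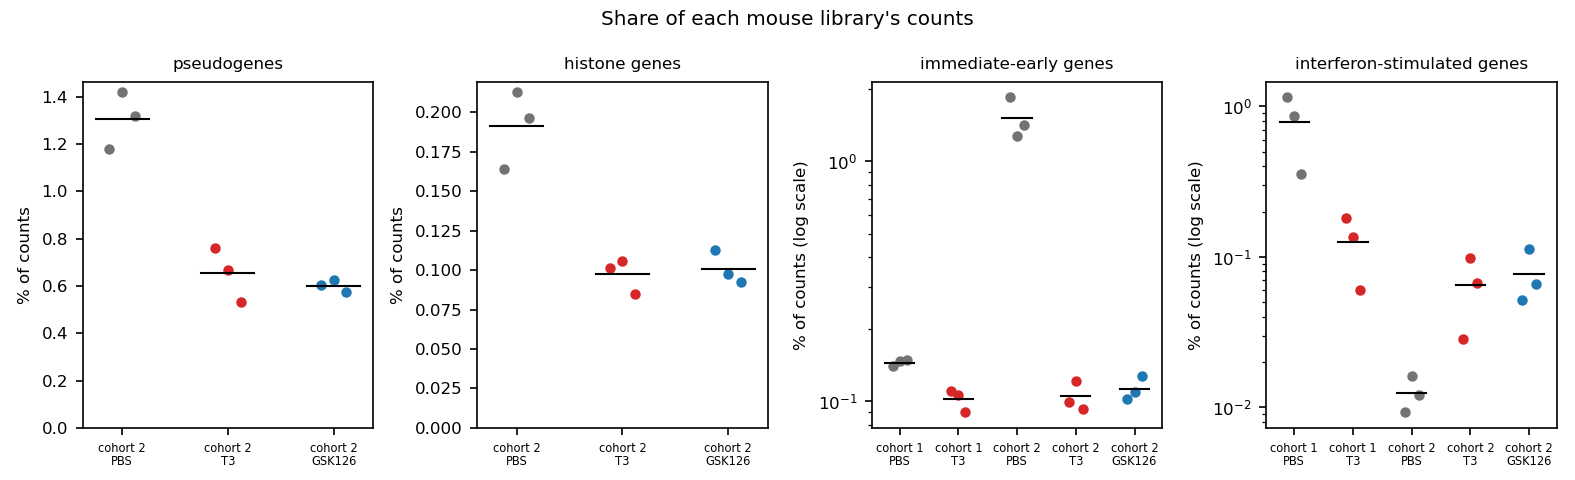
Share of all counts, in percent, taken by pseudogenes, histone genes and lists of immediate-early and interferon-stimulated genes chosen after the data were seen, in each mouse library, with lines at the group means. Immediate-early genes took 1.51% in the PBS libraries of cohort 2, 0.105% with T3 and 0.113% with GSK126.

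Markers of astrocytes and vessels fell with T3 in cohort 2 beside these lists. Of 16 astrocyte and glial progenitor markers 8 fell and none rose (9 fell adjusted over the list alone), with the water channel gene Aqp4 at 0.178 ± 0.21 CPM against 20.5 ± 12 (-6.77), Aldh1l1 (-5.12), Fgfr3 (-3.83) and Aldoc (-2.73). Of 12 endothelial and mural markers 10 fell (11 adjusted over the list alone), with Flt1 (-5.24), Rgs5 (-4.63), Kcnj8 (-2.96) and Kdr (-2.48). The medians were -1.92 and -2.57 (adjusted p = 0.00107 and 0.000222, and adjusted p = 0.504 for each with an estimated correlation). All 3 erythroid markers tested fell, also adjusted over the list alone, with the globin gene Hba-a2 (-4.62). Of 17 microglia and macrophage markers 4 fell (2 adjusted over the list alone; median -0.89, adjusted p = 0.245), with Cx3cr1 (-3.43) and P2ry12 (-3.77). Of 11 fibroblast and meningeal markers 3 fell, also adjusted over the list alone (adjusted p = 0.154, and 0.0306 without T3 2, in a range of 2.81e-05 to 0.623), with Fn1 (-1.60) and Vtn (-4.35). Of 14 oligodendrocyte lineage markers 1 fell, none adjusted over the list alone (median -0.91, adjusted p = 0.0756), and the list was called without PBS 1 (0.0259) or T3 2 (0.012), in a range up to 0.619. Of 7 GABAergic neuron markers 2 rose, also adjusted over the list alone, namely Pcp4 and Pvalb (1.51), with a median of -0.75 while the test pointed up (adjusted p = 0.728).

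The remaining lists were not called for T3 in cohort 2. Of 19 thyroid hormone responsive genes 6 rose and 2 fell, also adjusted over the list alone (median 0.57, adjusted p = 0.138), with Klf9 and Fndc5 (2.34). Of 14 thyroid hormone receptor, transport and metabolism genes 3 rose and 3 fell (3 and 5 adjusted over the list alone; adjusted p = 0.564). Of 21 granule neuron differentiation genes 6 rose and 3 fell (adjusted p = 0.462), with Etv1 (-1.93) and Nfia (-0.79) among those that fell. Of 54 axon guidance genes 17 rose and 8 fell (adjusted p = 0.309), with Ephb1 (2.24) and Plxnb1 (-1.29), and of 34 ion channel genes 9 rose and 2 fell (adjusted p = 0.0756), with Cacna2d3 (2.71). The channel list was called without PBS 2 (0.0374) or T3 2 (0.0306), in a range of 1.68e-06 to 0.566, and counts adjusted over the list alone were the same for these 3 lists. Of 30 glutamate and GABA receptor genes 9 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.368), with Gabbr2 (2.86) and Grin3a (-2.12). Of 46 cell cycle genes 6 rose and 3 fell (adjusted p = 0.564), with Ccne2 (1.12) and Cdk6 (-1.36), and of 26 stress genes 6 rose and 11 fell (adjusted p = 0.313), with Gclm (0.84) and Herpud1 (-1.31). Of 13 PRC2 subunit genes 4 rose and 3 fell (5 and 4 adjusted over the list alone), with Jarid2 (0.82) and Ezh1 (-0.75), a median of -0.07 and a test pointing up (adjusted p = 0.817). Of 25 Polycomb-repressed regulators 3 fell (adjusted p = 0.368), and of 7 photoreceptor and Group 3 markers 4 rose (adjusted p = 0.0956), with Gnb3 (3.07). In these last and in the cell cycle and stress lists the counts adjusted over the list alone were the same.

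GSK126 against PBS in cohort 2 asked what inhibiting EZH2 does in the same cells. Neurod1 rose by 1.34 (SE 0.219, adjusted p = 0.00257), to 711 ± 166 CPM from 280 ± 37 (n = 3), and Gli1 changed by -2.52 (SE 0.537, adjusted p = 0.00859), to 64.9 ± 37.4 CPM from 374 ± 44.8. Hr moved the other way from its change with T3, by -2.50 (SE 0.506, adjusted p = 0.0068), to 8.35 ± 4.08 CPM from 47.3 ± 23.6. Klf9 (0.68, adjusted p = 0.00636) and Thra (1.32, adjusted p = 0.000911) rose, while Thrb (0.96, adjusted p = 0.0944) and Rbfox3 (0.08, adjusted p = 0.687) missed the threshold. Ezh2, the gene of the inhibited enzyme, was at 202 ± 54.8 CPM against 190 ± 10.6 (0.09, adjusted p = 0.729), and Atoh1 was at -0.08 (adjusted p = 0.869). Mki67 changed by -0.52 (adjusted p = 0.0453), a call lost without GSK126 2 (0.12), GSK126 3 (0.133), PBS 1 (0.123), PBS 2 (0.0911) or PBS 3 (0.0825), in a range over its alternatives of 0.0105 to 0.865. Of 15753 genes tested, 2996 rose and 2716 fell, and in 50% the groups did not overlap (chance, 10%).

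The lists called with GSK126 were largely those called with T3. Of 28 pan-neuronal genes 20 rose and none fell (21 rose adjusted over the list alone), with Syt1 (3.2), Syn2 (1.72), the microtubule protein gene Mapt (1.68) and Stmn2 (1.40), and of 34 ion channel genes 11 rose and 1 fell, also adjusted over the list alone, with Kcnd3 (2.40) and Scn3b (1.66). Of 25 cholesterol synthesis genes 23 rose, also adjusted over the list alone, with Hmgcs1 (2.72), Msmo1 (2.29), Tm7sf2 (1.43) and Lss (1.14). Of 24 p53 targets 14 rose and 1 fell (15 and 1 adjusted over the list alone), with Trp53inp1 (2.15) and Btg2 (-2.21). The medians were 0.82, 0.51, 1.42 and 0.62 with camera adjusted p = 1.11e-06, 0.00307, 1.16e-08 and 0.000974. Of 18 SHH pathway genes 8 fell, also adjusted over the list alone, with Hhip (-1.94), Ptch1 (-1.68) and the co-receptor gene Boc (-1.29). Of 28 MYC target and ribosome biogenesis genes 20 fell and 3 rose (21 and 3 adjusted over the list alone), with Myc (-1.82), Ppan (-1.65), Gnl3 (-1.0) and Mybbp1a (-0.77). Their medians were -1.0 and -0.67 with adjusted p = 0.00409 and 6.79e-06. Each of these 6 lists had adjusted p = 0.388 with an estimated correlation. The largest falls among eligible genes were in H2ac24, Fosb, Klf4, Klf2, Egr1 (-6.93, SE 0.668) and Fos (-6.62).

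Markers of astrocytes and vessels fell with GSK126. Of 16 astrocyte and glial progenitor markers 5 fell, also adjusted over the list alone, with Aqp4 (-4.72), Fgfr3 (-3.60) and Aldh1l1 (-2.77), and of 12 endothelial and mural markers 6 fell, also adjusted over the list alone, with Rgs5 (-4.71), Flt1 (-3.55), Kcnj8 (-3.41) and Abcc9 (-3.31). Their medians were -1.25 and -2.03 (adjusted p = 0.00601 and 0.000974, with adjusted p = 0.405 and adjusted p = 0.388 with an estimated correlation). Of 17 microglia and macrophage markers 3 rose, also adjusted over the list alone (median 0.42, adjusted p = 0.245, and 0.0151 without PBS 2, in a range up to 0.766), with the lysosomal protein gene Cd68 (2.35) and Ptprc (2.18). Cd68 missed the threshold without GSK126 2 (0.0546), PBS 1 (0.0569) or PBS 3 (0.0586), and Ptprc without GSK126 2 (0.0501), in ranges of 0.00023 to 0.0748 and 0.000122 to 0.0715. The largest rises of eligible genes included Lgals3 (4.42, SE 0.841), H2-Q7 (4.10), Diras2 (4.03), the oxidase subunit gene Cybb (4.0), the complement receptor gene C3ar1 (3.98) and Cemip (3.92). All 3 erythroid markers tested fell, also adjusted over the list alone, with the globin genes Hbb-bs (-7.40) and Hba-a2 (-5.12). Of 14 oligodendrocyte lineage markers none was called by edgeR, of 11 fibroblast and meningeal markers 1 rose and 3 fell, also adjusted over the list alone, with Pdpn (1.45) and Vtn (-4.03), and of 7 GABAergic markers 1 rose, also adjusted over the list alone, namely Pcp4 (2.02). Pcp4 missed the threshold without GSK126 3 (0.0528) or PBS 1 (0.0537), in a range of 0.00019 to 0.0751. Camera gave adjusted p = 0.245, 0.53 and 0.595 for these last 3 lists, and the GABAergic median was -0.04 while the test pointed up.

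Polycomb targets and PRC2 genes did not move in 1 direction as groups with GSK126 by camera, while fry in mixed direction called both (adjusted p = 0.000216 and 1.81e-06, in ranges up to 0.889 and 0.909). Of 25 Polycomb-repressed developmental regulators, 96 being listed and the others not tested, 1 rose and 3 fell (none and 2 adjusted over the list alone; median -0.06, adjusted p = 0.595), with Foxa2 (-2.34) and En2 (-0.48). Foxa2 missed the threshold without GSK126 3 (0.0587) and En2 without GSK126 2 (0.0594), in ranges of 0.000115 to 0.0587 and 0.00358 to 1. Of 13 PRC2 subunit genes 2 rose and 2 fell, also adjusted over the list alone, with Jarid2 (0.68), a median of 0.08, a mean of -0.03 and a test pointing down (adjusted p = 0.844). Of 19 granule neuron progenitor genes 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0599), with Mfap4 (-3.69) and Id1 (-2.71), and that list was called without GSK126 1 (0.0373) or PBS 3 (0.045), in a range of 1.79e-08 to 0.388. Of 30 glutamate and GABA receptor genes 11 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0599), with Grin2b (2.2), and that list was called without GSK126 1 (0.0359) or GSK126 3 (0.04), in a range of 1.97e-05 to 0.388. Of 46 cell cycle genes 12 fell and 2 rose (7 and none adjusted over the list alone; adjusted p = 0.133, and 4.2e-05 without GSK126 1, in a range up to 0.966), with Cdk6 (-1.02) and Cdc25a (-0.76). Of 54 axon guidance genes 17 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.123), with Ephb1 (1.75). Of 21 granule neuron differentiation genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.263), with Nfia (-0.74). Of 19 thyroid hormone responsive genes 6 rose and 5 fell (adjusted p = 0.53), with Nrp1 (1.71) and Flywch2 (-2.36), and of 14 receptor, transport and metabolism genes 3 rose and 5 fell (adjusted p = 0.348), with the transporter gene Slc16a10 (1.60). Of 26 stress genes 5 rose and 11 fell (6 and 12 adjusted over the list alone; adjusted p = 0.492), and of 7 photoreceptor markers 3 rose (adjusted p = 0.142). For the photoreceptor list and both hormone lists the counts adjusted over the list alone were the same.

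T3 against GSK126 asked where the compounds differ, and 5 genes separated them in the fit without pairs and 53 with the replicate block. Syt12, a synaptotagmin of neurons, was higher with T3, at 53.2 ± 13.1 CPM against 7.89 ± 0.488 (2.75, SE 0.181, adjusted p = 0.00107, n = 3). Sema3c, a secreted guidance signal (4.97, SE 0.592, adjusted p = 0.0375), and Pcx, the gene of pyruvate carboxylase (1.05, SE 0.0884, adjusted p = 0.00476), were also higher with T3. Aldh2 (-1.66, SE 0.182, adjusted p = 0.0325) and Actn1 (-0.87, SE 0.103, adjusted p = 0.0375) were lower. Hr was at 156 ± 60.6 CPM with T3 and 8.35 ± 4.08 with GSK126 (4.22, SE 0.535, 95% interval 3.00 to 5.44), with adjusted p = 0.0635, in a range over its alternatives from 4.74e-20 with DESeq2 to 0.353. In a fit of these 6 libraries alone with the replicate block, chosen after the data were seen, Hr passed the threshold (4.24, adjusted p = 2.86e-05). Klf9 differed by 0.93 (SE 0.141, adjusted p = 0.11), and by the replicate block it passed the threshold (adjusted p = 0.0204, in a range of 1.76e-06 to 1). Actn1 lost its call without any 1 library, at adjusted p of 0.186 (T3 1), 0.172 (T3 2), 0.187 (T3 3), 0.0625 (GSK126 1), 0.167 (GSK126 2) and 0.147 (GSK126 3). Sema3c lost it without T3 1 (0.152), T3 2 (0.151), T3 3 (0.178), GSK126 1 (0.0681) or GSK126 3 (0.163), and Aldh2 without T3 1 (0.152), T3 2 (0.0504), T3 3 (0.178), GSK126 2 (0.0859) or GSK126 3 (0.0656). The ranges over the alternatives were 1.71e-08 to 1 for Actn1, 1.14e-14 to 0.178 for Sema3c and 1.75e-12 to 0.178 for Aldh2. For Neurod1 the difference was -0.10 (95% interval -0.58 to 0.39) and for Gli1 0.15 (-1.02 to 1.32). Rbfox3 (0.38), Thra (-0.26), Thrb (0.87), Atoh1 (0.41), Mki67 (-0.18) and Ezh2 (0.24) missed the threshold, at adjusted p from 0.369 to 0.686.

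Of 15753 genes, 3 were higher and 2 lower with T3 than with GSK126, 1886 had an unadjusted p under 0.05, and in 18.9% the groups did not overlap (chance, 10%). With the replicate block on all cohort 2 libraries 53 genes were called, with the block on these 6 libraries alone, a fit chosen after the data were seen, 384, and with DESeq2 137. Leaving out T3 1, T3 2 or T3 3 gave 2 genes each, GSK126 2 or GSK126 3 gave 3 each, and GSK126 1 gave 11. Microglia and macrophage markers were lower with T3 than with GSK126 (median -1.41 over 17 genes, adjusted p = 9.52e-07), and cell cycle genes (0.24 over 46, adjusted p = 2.35e-06) and MYC target and ribosome biogenesis genes (0.19 over 28, adjusted p = 0.000856) were higher. Each had adjusted p = 0.693 with an estimated correlation, and no member of these lists was called, adjusted over the list alone or over all genes. The cell cycle call was lost without GSK126 3 (0.0957, in a range of 8.17e-22 to 0.693), and by fry with the block the microglia list was called (0.0126, in a range of 1.41e-14 to 0.693) and the cell cycle and MYC target lists were not (0.373 each, in a range from 1.54e-06 to 0.693 for MYC targets). The astrocyte list was at a median of -0.50 (adjusted p = 0.0576, and 0.0366 with the block, in a range of 0.00153 to 0.693), and of 19 thyroid hormone responsive genes 4 were higher adjusted over the list alone and none over all genes (adjusted p = 0.105, and 0.0165 by fry with the block, in a range of 5.06e-07 to 0.693). The other lists were not called and held 1 called member, Sema3c among 54 axon guidance genes (adjusted p = 0.105), with 1 pan-neuronal, 1 p53 target, 1 photoreceptor and 2 GABAergic genes higher adjusted over the list alone. The GABAergic median was -0.66 and the receptor, transport and metabolism median -0.01 while both tests pointed up. Leaving out T3 2 raised the number of lists called from 3 to 8, GSK126 3 to 7, and T3 3 or GSK126 2 to 5. The block on these 6 libraries alone also called the ion channel (0.0124), glutamate and GABA receptor (0.0343), axon guidance (0.0425) and fibroblast (0.0431) lists, each lower with T3, and not the astrocyte list (0.0614).

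**Figure D3:**
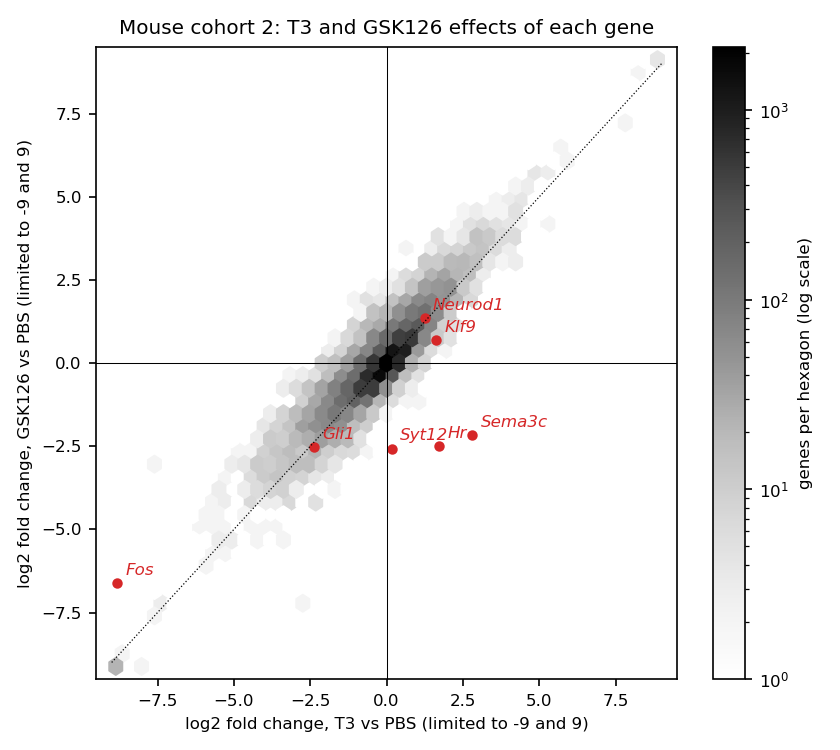
Log2 fold change with GSK126 against that with T3, each over the shared PBS libraries of cohort 2, for 15753 genes, shaded by the number of genes and limited to -9 and 9. Most genes lie near the diagonal (r = 0.893 across genes), and Hr lies far from it.

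The changes with T3 and with GSK126 resembled each other across genes, as compared with the same PBS libraries. The correlation across 15753 genes was 0.893 (Spearman 0.866), where unchanged groups simulated against shared controls gave 0.507 and 0.459, and the covariance was 1.51 against 0.115 simulated, a difference of 1.40. Genes are not independent replicates, so no p is given. There were 2216 genes that rose with both and 2026 that fell with both, and 3 called in opposite directions. Independent lists would share 547.5 and 470.7. Unchanged groups simulated likewise shared 0, but they allow hardly any call, so that 0 sets no background. The simulation held no shift of the PBS group and no pairing of T3 with GSK126. The real data showed both, so simulated values may be too low. Part of the excess may come from this pairing or the shared controls, too few to be split. Between cohorts 1 and 2, which share no library, the correlation of T3 effects across 13987 genes was 0.338 (Spearman 0.316). The T3 effects of cohort 1 correlated with those of GSK126 against PBS at 0.365 (Spearman 0.385) and with T3 against GSK126 at -0.0635 (Spearman -0.149, and -0.165 over genes with a mean log2 CPM of at least 3), so the resemblance between cohorts was not special to T3. With T3, 958 genes rose in both cohorts and 704 fell in both (446.4 and 407 for independent lists), while 348 moved in opposite directions (866.7).

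**Figure D4:**
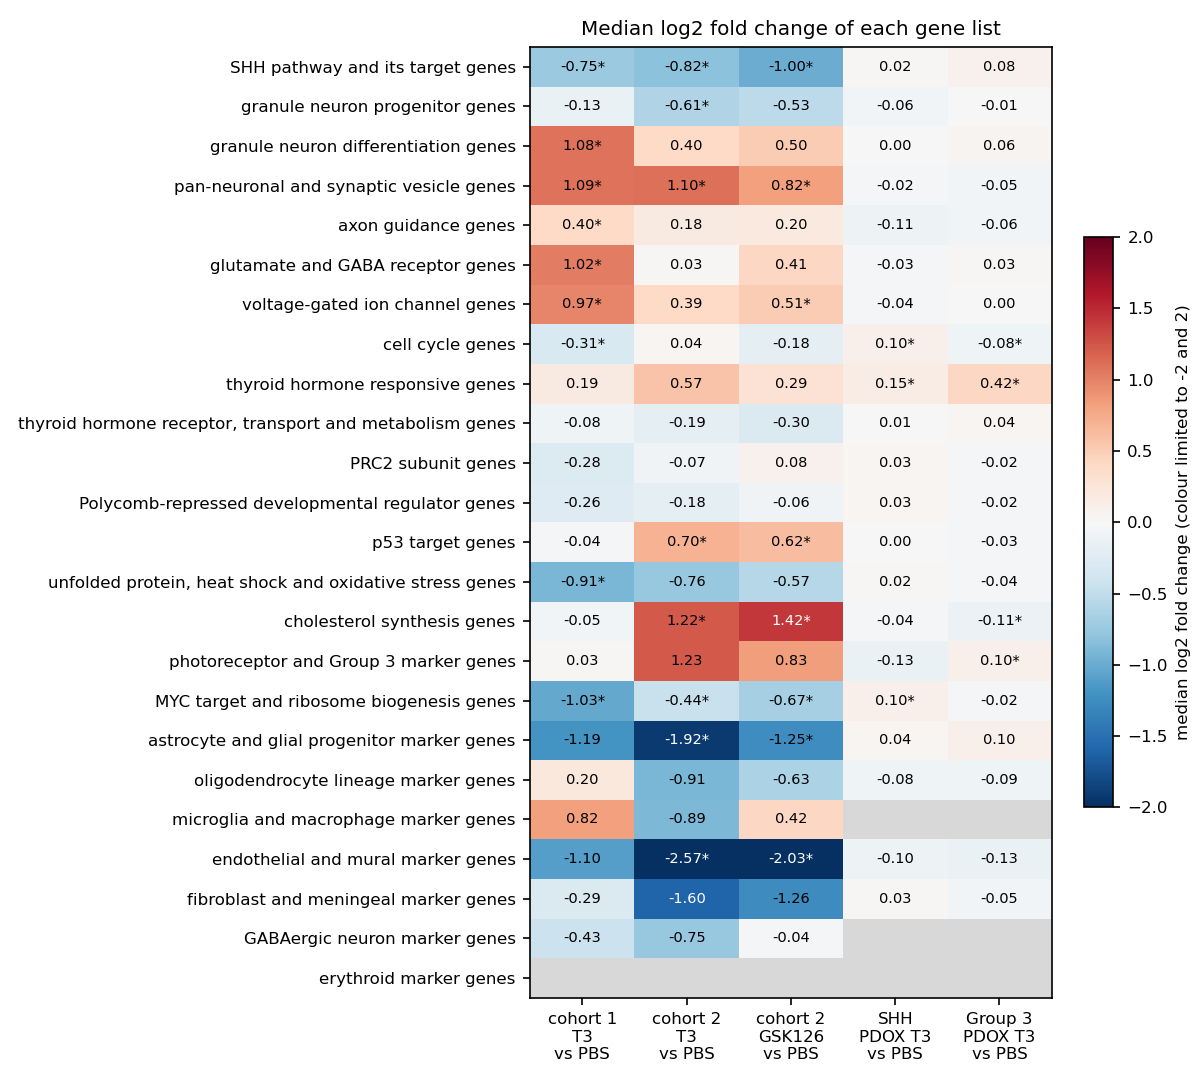
Median log2 fold change of each gene list in 5 comparisons, with an asterisk where camera's adjusted p was under 0.05 at the preset correlation and grey where fewer than 5 members were tested. The pan-neuronal list stood at 1.09 and 1.10 with T3 in the mouse cohorts and at -0.02 in the SHH line.

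In the SHH line T3 was asked to show whether human tumour cells respond as mouse cells do. HR rose by 3.84 (SE 0.08, adjusted p = 2.21e-45), to 92.2 ± 7.91 CPM from 6.44 ± 0.593 (n = 3), and KLF9 by 1.26 (SE 0.0581, adjusted p = 6.77e-28). NEUROD1 stayed at 132 CPM in both groups (0.01, 95% interval -0.07 to 0.09, adjusted p = 0.932). GLI1 changed by -0.38 (SE 0.0797, adjusted p = 0.000401), to 23.1 ± 0.993 CPM from 30.1 ± 1.52, and MKI67 rose by 0.26 (SE 0.0413, adjusted p = 3.27e-06). RBFOX3 rose by 0.16 (adjusted p = 0.0174), a call lost without T3 2 (0.0531), T3 3 (0.161), PBS 1 (0.102) or PBS 2 (0.166) and with DESeq2 (0.117), in a range of 0.00297 to 1. ATOH1, THRA, THRB and EZH2 lay between -0.05 and 0.05, at adjusted p from 0.48 to 0.994. The largest rises after HR among eligible genes included the endothelin receptor gene EDNRB (2.36, SE 0.0507), the tight junction gene CLDN5 (2.24), SORL1 (1.56) and ARC (1.56), and the largest falls were in RAP1GAP (-1.12), COL6A3 (-1.06), TGFB2 (-0.73), RNF24 (-0.71), ISYNA1 (-0.60) and SOD3 (-0.59). Of 14972 genes tested 641 rose and 515 fell, 35 and 16 of them by at least 2-fold, and in 23.5% the groups did not overlap (chance, 10%). The common dispersion was 0.00166 here and 0.0884 in cohort 1. Changes far under 2-fold thus passed the threshold, and the p-values may measure technical spread in part. DESeq2 called 669 genes and a joint fit with the Group 3 line 123, in which the calls of GLI1 (0.121) and MKI67 (0.306) were lost, in ranges of 0.000187 to 1 and 9.18e-08 to 1.

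Thyroid hormone responsive, cell cycle and MYC target genes rose with T3 in the SHH line. Of 18 thyroid hormone responsive genes 6 rose (7 adjusted over the list alone), with HR, KLF9, the clock output gene DBP (1.15) and PTGDS (1.13), and the median was 0.15 (adjusted p = 1.62e-05). Of 46 cell cycle genes 11 rose and 1 fell (20 and 1 adjusted over the list alone), with CCNE2 (0.36), TOP2A (0.30) and RRM2 (0.25), and the median was 0.10 (adjusted p = 2.36e-08). Of 28 MYC target and ribosome biogenesis genes 5 rose (10 adjusted over the list alone), with DDX21 (0.17) and ODC1 (0.13), and the median was 0.10 (adjusted p = 7.7e-05). Each of these 3 had adjusted p = 0.0541 with an estimated correlation. Of 17 SHH pathway genes 4 rose and 4 fell, also adjusted over the list alone (median 0.02, adjusted p = 0.965), with SMO (0.41) and SFRP1 (-0.24). Of 27 pan-neuronal genes 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.803), with CPLX1 (0.26) and STMN2 (-0.22), and of 21 granule neuron differentiation genes 1 fell (2 adjusted over the list alone; adjusted p = 0.965), namely CNTN1 (-0.16), which missed the threshold without PBS 1 (0.0706, in a range of 0.00264 to 1). Of 16 progenitor genes 1 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.123), with MFAP4 (-0.49) and SOX2 (-0.15).

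**Figure D5:**
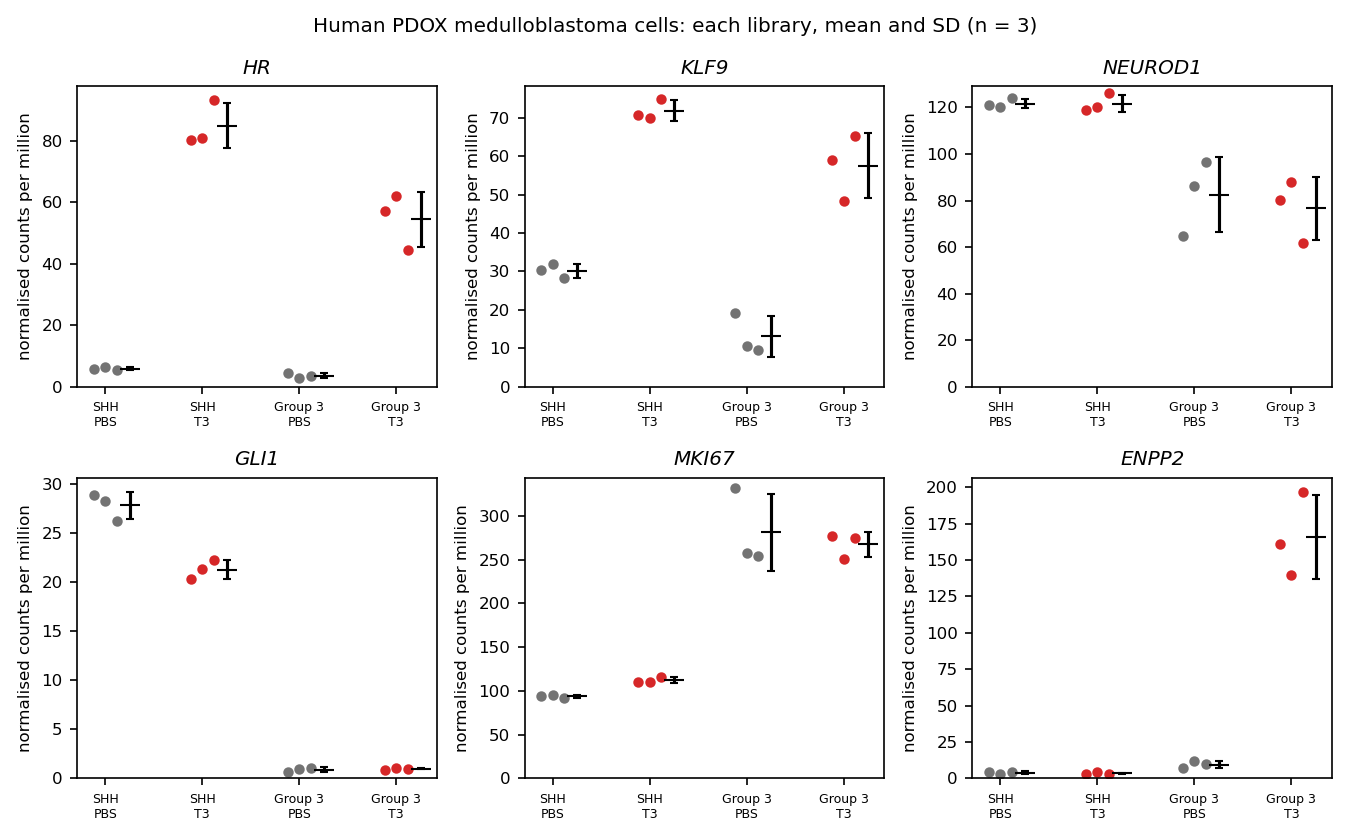
Normalised CPM of 6 genes in each PDOX library, with points for libraries and lines for group means, and both lines normalised together, so that values differ slightly from those in the text. HR rose in both lines and ENPP2 in the Group 3 line.

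Other lists were not called in the SHH line. Of 46 axon guidance genes 6 rose and 6 fell (6 and 10 adjusted over the list alone; adjusted p = 0.123), with the netrin receptor gene UNC5B (1.00) and SEMA7A (-0.26), and of 36 ion channel genes 6 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.965), with KCNA1 (-0.33). Of 26 stress genes 2 fell, also adjusted over the list alone, namely HSPB1 (-0.42) and HSPA1A (-0.22), while the list's median was 0.02 and the test pointed up (adjusted p = 0.965). Of 11 astrocyte markers 1 rose and 4 fell (2 and 4 adjusted over the list alone; adjusted p = 0.504), with FABP7 (-0.22) and GLUL (0.13), and of 8 oligodendrocyte lineage markers 1 rose and 1 fell (adjusted p = 0.504), CLDN11 (0.16) and CSPG4 (-0.34). Of 8 endothelial and mural markers 1 rose and 1 fell, CLDN5 and PDGFRB (-0.45), with a median of -0.10, a mean of 0.17 and a test pointing down (adjusted p = 0.803). Of 10 fibroblast markers 1 fell, PDPN (-0.18; adjusted p = 0.965), of 27 receptor genes 1 fell, GRIK1 (-0.37; adjusted p = 0.623), and of 13 PRC2 subunit genes 1 rose and 1 fell (adjusted p = 0.965), with PHF1 (-0.25). GRIK1 missed the threshold without T3 2 (0.155) or PBS 3 (0.243), in a range of 0.0178 to 1. Of 29 Polycomb-repressed regulators 1 rose, DLX5 (0.69; adjusted p = 0.486), and of 17 receptor, transport and metabolism genes 1 rose and 1 fell (adjusted p = 0.965). For these 6 lists and the oligodendrocyte list counts adjusted over the list alone were the same. No p53 target (24), cholesterol synthesis (24) or photoreceptor gene (10) was called, adjusted over the list alone or not (adjusted p = 0.965, 0.512 and 0.309). Median and test differed in sign for the granule neuron differentiation, astrocyte, fibroblast, p53 and receptor, transport and metabolism lists, whose medians lay between 0.00 and 0.04. Microglia (4 tested) and GABAergic (4 tested) markers were too few to test, though ITGAM rose (0.63), and no erythroid marker was tested.

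In the Group 3 line the hormone-responsive genes HR and DBP were called as higher with T3, and few other genes were called. HR rose by 3.91 (SE 0.191, adjusted p = 0.000379), to 50.3 ± 8.15 CPM from 3.35 ± 0.84 (n = 3), and it was the only one of 13 called named genes that kept its call in every alternative. ENPP2, the gene of the lysophosphatidic acid enzyme autotaxin, rose by 4.13 (SE 0.216, adjusted p = 0.00231), to 153 ± 26.7 CPM from 8.71 ± 2.41, and missed the threshold without PBS 3 (0.0568, in a range from 7.08e-113). FRY (1.56), NEAT1 (1.52), ANTXR1 (1.3), PEX5L (1.17), UNC5B (1.02) and DBP (0.79) also rose, and SEMA5B (-0.81), the serotonin receptor gene HTR1A (-0.70), KLHDC8A (-0.59), NSG2 (-0.51) and NBL1 (-0.40) fell. Each of these 11 lost its call without T3 1 (adjusted p from 0.087 to 0.364) or PBS 3 (0.0568 to 0.181), and each but NEAT1 without PBS 2 (0.0741 to 0.259). All but KLHDC8A and NEAT1 lost it without T3 2 (0.0566 to 0.141), and DBP, HTR1A, NBL1 and NSG2 without T3 3 (0.062 to 0.176). Over all alternatives their adjusted p ranged from 1.18e-16, for NEAT1, to 1, for 6 of them. KLF9 was at 53.1 ± 7.91 CPM against 12.1 ± 4.97 (2.13, SE 0.273, adjusted p = 0.0523, and 0.000172 without PBS 1, in a range of 1.6e-16 to 0.381). NEUROD1 (-0.11), RBFOX3 (0.10), MKI67 (-0.07), EZH2 (-0.06), THRA (0.01) and GLI1 (0.12, at under 1 CPM) were at adjusted p from 0.913 to 0.989.

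Of 13967 genes tested in the Group 3 line 32 rose and 6 fell, 918 had an unadjusted p under 0.05, and in 12.5% the groups did not overlap (chance, 10%). The libraries PBS 1 and T3 3 stood apart from the others of their groups, and without both, a choice made after the data were seen, 377 genes were called. Leaving out PBS 1 gave 106 calls, T3 3 gave 16, T3 2 gave 5, PBS 2 gave 4, T3 1 gave 2 and PBS 3 gave 1. Thyroid hormone responsive genes rose as a list, with 2 of 14 called (4 adjusted over the list alone), a median of 0.42 and adjusted p = 2.09e-07. Cell cycle genes were lower, with none of 46 called over all genes and 8 lower and 1 higher adjusted over the list alone (median -0.08, adjusted p = 2.21e-05). Photoreceptor and Group 3 markers were higher, with none of 19 called and 2 adjusted over the list alone (median 0.10, adjusted p = 0.0159), a call lost without T3 1 (0.0738), T3 2 (0.0765) or PBS 1 (0.232), in a range of 0.0186 to 0.353. Each of these 3 had adjusted p = 0.264 with an estimated correlation. Cholesterol synthesis genes were lower, with none of 24 called, adjusted over the list alone or not (median -0.11, adjusted p = 0.00504, and adjusted p = 0.533 with an estimated correlation), and without T3 3 (0.155) or PBS 1 (0.0679) the call was lost, in a range of 0.000302 to 0.661. Of 43 axon guidance genes 1 rose and 1 fell (1 and 2 adjusted over the list alone; adjusted p = 0.568), UNC5B and SEMA5B. The other lists had no member called by edgeR over all genes, and adjusted over the list alone 2 progenitor, 2 granule neuron differentiation, 1 receptor, 1 channel and 1 PRC2 gene were higher and 1 differentiation and 1 stress gene lower. Median and test differed in sign for the progenitor (-0.01) and Polycomb (-0.02) lists, whose tests pointed up, and the channel list (0.00), whose test pointed down. Endothelial markers were called without T3 3 (0.0191, in a range up to 0.753).

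The difference of the T3 effect between the PDOX lines was tested directly, as the effect in the SHH line minus that in the Group 3 line. For HR it was -0.08 (SE 0.228, 95% interval -0.57 to 0.42, adjusted p = 0.971) and for KLF9 -0.88 (SE 0.283, adjusted p = 0.313). ENPP2 differed by -4.29 (SE 0.351, adjusted p = 0.000404), being at -0.15 in the SHH line and 4.13 in the Group 3 line. RASGEF1B, a guanine nucleotide exchange factor gene, differed by 1.33 (SE 0.116, adjusted p = 4.45e-05) and PWWP2B by 1.14 (adjusted p = 0.0025). HTRA1 (0.87), FAM184B (0.86), FRMD6 (-1.42), FRY (-1.46) and IGFBP4 (-1.10) were the other genes with large differences, and SMO (0.47) and MFAP4 (-0.79) were called as well. MKI67 (0.32), NEUROD1 (0.11) and GLI1 (-0.51) were at adjusted p from 0.364 to 0.935. Of 15910 genes 19 had a higher and 23 a lower effect in the SHH line, and 1535 had an unadjusted p under 0.05. HTRA1 and FAM184B lost their calls without the SHH library PBS 1 (0.0512 each), and HTRA1 also without PBS 2 (0.0529). IGFBP4 lost its call without any library but the Group 3 PBS 1 and T3 3 (0.0521 to 0.102), FRY without any SHH library (0.054 to 0.0687) or the Group 3 T3 1 (0.0585), and FRMD6 without any SHH library but T3 1 (0.0512 to 0.06). SMO lost it without the SHH libraries PBS 1 (0.0512), PBS 2 (0.0529) or T3 2 (0.06), and KLF9 gained one without the Group 3 PBS 1 (0.00025). Over the alternatives these genes ranged in adjusted p from 2.93e-06, for FRY, to 1, for 5 of the 7. Leaving out SHH libraries gave 12 (PBS 1), 15 (T3 2), 16 (PBS 2), 17 (PBS 3), 20 (T3 3) and 25 (T3 1) calls, and leaving out Group 3 libraries gave 279 (PBS 1), 89 (T3 2) and 22 (T3 1).

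Cell cycle genes differed between the lines, with an effect higher in the SHH line by a median of 0.20 over 46 genes (adjusted p = 5.2e-16, and adjusted p = 0.00527 with an estimated correlation). Camera also gave p under 0.05 for this list in 53 of 100 splits of these libraries, the labelled one included, so how far its p can be relied on is open. E2F2 (0.66) and UHRF1 (0.39), which act at the start and in the course of DNA replication, were called, and 17 genes adjusted over the list alone. Both lost their calls without any 1 of the SHH libraries (0.0632 to 0.156) and without the Group 3 PBS 2, PBS 3, T3 1 or T3 3 (0.0514 to 0.0619), in ranges of 0.000479 to 1 for E2F2 and 0.000102 to 1 for UHRF1. MYC target and ribosome biogenesis genes also had a higher effect in the SHH line (median 0.12 over 28, none called, adjusted p = 0.000327, and adjusted p = 0.0901 with an estimated correlation). Photoreceptor and Group 3 markers had a lower one (median -0.40 over 21, none called, adjusted p = 0.0057, and adjusted p = 0.0682 with an estimated correlation), a call lost without the Group 3 library PBS 1 (0.064, in a range of 0.00134 to 0.129). For 18 granule neuron progenitor genes the median was -0.14, with 1 called and 2 adjusted over the list alone (adjusted p = 0.0274, and adjusted p = 0.399 with an estimated correlation). That call was lost without the SHH libraries PBS 3 (0.0751) or T3 1 (0.0795) or the Group 3 libraries PBS 2 (0.118), PBS 3 (0.141) or T3 3 (0.0901), in a range of 0.000896 to 0.399. Cholesterol synthesis genes were called without the Group 3 library T3 2 (0.0104, in a range up to 0.681). Of 18 SHH pathway genes 1 had a higher effect in the SHH line, SMO (3 higher and 2 lower adjusted over the list alone; median -0.29, adjusted p = 0.553), and the other lists had none called over all genes.

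T3 effects were compared across genes between the lines and between species. Of 35 genes called in the Group 3 line and tested in both lines, 13 rose in both, among them HR, DBP, UNC5B and ANTXR1, and 3 fell in both, KLHDC8A, SEMA5B and NSG2, where independent lists would share 1.33 and 0.173, and 1 was called in opposite directions. Across 13088 genes the correlation of T3 effects between the lines was 0.0879 (Spearman 0.0304), and 0.226 over genes with a mean log2 CPM of at least 3. Between mouse cohort 2 and the SHH line the correlation was 0.0175 across 11477 genes, and between cohort 2 and the Group 3 line 0.0464 across 10849 (0.0725 over the higher genes). Between cohort 1 and the SHH line it was -0.0444 across 11420 (Spearman -0.0951, and -0.077 over the higher genes), with 265 genes called in opposite directions where independent lists would give 194.9, and between cohort 1 and the Group 3 line 0.0278 across 10763 (0.0455 over the higher genes). The differences between species were not tested.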

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

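Tests chosen only after the result was seen are those of library making, of cell loss, of microglia and of T3 having 1 direction, and the use of the estimated correlation as such a test, while the fits without libraries standing apart were added after the data were seen but before their own results, and the splits were chosen before, with their count by how T3 is parted chosen after.

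The results below were picked out because the T3 effect differed between the PDOX lines in a test of the difference itself, as it did for 42 genes. Among lists these were cell cycle genes (median difference 0.197), MYC target and ribosome biogenesis genes (0.115), granule neuron progenitor genes (-0.14) and photoreceptor and Group 3 markers (-0.404), of which only the first held with an estimated correlation (adjusted p = 0.0901, 0.399 and 0.0682 for the others). Among genes with higher effects in the SHH line these were RASGEF1B (1.33), PWWP2B (1.14), HTRA1 (0.87) and FAM184B (0.86). Among genes with higher effects in the Group 3 line these were ENPP2 (-4.29), FRY (-1.46), FRMD6 (-1.42) and IGFBP4 (-1.10). MKI67 was picked out because all libraries with T3 lay below PBS in mouse cohort 1 (-0.52) and cohort 2 (-0.70) and above PBS in the SHH line (0.26), a difference between species that was not tested.

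The PBS libraries of mouse cohort 2 stood apart from both the T3 and the GSK126 libraries. The lowest pseudogene share of a PBS library was 1.55 times the highest of a treated library, which is part of the pattern itself, so a difference in library making or quantification cannot be told apart from other causes by it. As a difference special to cohort 2 that makes up the whole pattern, such a difference is argued against by the T3 effects of cohort 1, which shares no library and correlated with T3 effects in cohort 2 at 0.338 and with GSK126 effects at 0.365 across genes. A loss of endothelial cells and microglia to the same degree is argued against. The quartiles of their marker changes lay 0.432 apart with T3 and 1.27 apart with GSK126. An uneven loss of other cell types was not tested and stays open. With T3 the astrocyte (-1.92), oligodendrocyte (-0.91), microglia (-0.893), endothelial (-2.57) and fibroblast (-1.6) medians were all negative, and with GSK126 all of these but microglia (0.419). T3 against GSK126 correlated with cohort 1 at -0.0635, so what stays open is how much of the change against PBS in cohort 2 may come from the libraries, from something common to treated cultures of both cohorts, and from T3 itself.

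Interferon-stimulated genes fell with T3 in cohort 1 (21 of 28, median -3.07) and rose with T3 in cohort 2 (23 of 29, median 2.92). The pair numbered 3 in cohort 1, which stood apart and came from female mice, is argued against as the cause by a median of -3.16 without it. Fewer microglia and macrophages are argued against by the median of their markers in cohort 1, 0.822. These lists were chosen after the values were seen, and with an estimated correlation camera gave p = 0.291 and 0.191. An effect of T3 with 1 direction cannot be told apart from a difference between cultures or libraries, since opposite signs are the pattern itself and the PBS libraries of cohort 2 stood apart.

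Cell cycle genes differed in their T3 effect between the PDOX lines. The Group 3 libraries PBS 1 and T3 3, which stood apart, are argued against as the cause by a median difference of 0.217 without both and an adjusted p = 0.0117 with an estimated correlation (1.33e-14 with the preset one), and the preset correlation by an adjusted p = 0.00527 with an estimated one over all libraries. Of 100 splits of the libraries 1 gave a median difference as large, the labelled one, and the highest other was 0.16. Camera gave p under 0.05 in 53 of these splits (lowest other 9.13e-12), among them 34 of 40 that part T3 the same way in both lines and 0 of 40 that part it opposite ways, so parts of the T3 effect enter them and whether camera's p is too small stays open. A difference between the lines in how T3 acts on dividing cells may remain as a hypothesis, found and examined on the same data.

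Splits of the same libraries into other groups were counted for each comparison. In the 6 comparisons of 3 against 3 there are 10 splits, which cannot give a share under 0.05. The labelled split called 5348 genes and the highest other 0 for T3 in cohort 1, 5609 and 0 for T3 in cohort 2, 5712 and 1 for GSK126, and 1156 and 2 in the SHH line, each with 1 split as large, its own. For T3 against GSK126 it was 5 and 4 (1 split as large), where the highest other did not part all pairs. In the Group 3 line the labelled split called 38 and the highest other 122 (2 splits as large), a split that puts PBS 1 with T3 1 and T3 3, which points to structure of the samples. For the difference between the lines 13 of 100 splits called as many as the labels (highest other 634), so chance is not excluded for the count of 42 and the structure of the samples enters it.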

How the results depend on the processing

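Added after the data were seen were fits without the Group 3 PBS 1 and T3 3 or the pair numbered 3 of cohort 1. So were fits of protein-coding genes alone and of T3 and GSK126 libraries alone. No named gene turned its direction where it was called. Of named genes called, 56 of 77 kept their call in every alternative for T3 in cohort 1, 67 of 80 for T3 in cohort 2, 64 of 78 for GSK126, 1 of 5 for T3 against GSK126, 11 of 50 in the SHH line, 1 of 13 in the Group 3 line and 2 of 12 for the difference between lines. Except where noted the cause was not tested.

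The replicate block raised the count for T3 in cohort 1 from 5348 to 8585 and for T3 against GSK126 from 5 to 53, and to 384 with these libraries alone, where it called 7 lists in place of 3. In the fits of all groups, with edgeR and camera, it changed few calls of named genes and lists in the paired comparisons. These were Mki67, Ezh2 and Atoh1 in cohort 1 and Klf9 and the astrocyte list for T3 against GSK126. With T3 and GSK126 libraries alone it called Klf9, Hr and the channel, receptor, axon guidance and fibroblast lists besides, and not the astrocyte list. In the other comparisons libraries share only a number. Deviations correlated at 0.286, 0.27 and 0.0509 for PBS and T3 in cohort 2, 0.0887, 0.228 and 0.0416 for PBS and GSK126, 0.00455, 0.0699 and -0.0134 in the SHH line and -0.0182, 0.244 and -0.309 in the Group 3 line. There the block gave 6388 calls for T3 in cohort 2 in place of 5609, 6442 for GSK126 in place of 5712, 1090 in the SHH line in place of 1156, 6 in the Group 3 line in place of 38 and 22 for the difference in place of 42. With fry the block called 8 lists for T3 in cohort 1 in place of 12, where it lost the GABAergic, PRC2, astrocyte and endothelial lists, and 2 for T3 against GSK126 in place of 0, the thyroid hormone responsive and microglia lists. It called 16 lists for T3 in cohort 2, 15 for GSK126, 5 in the SHH line, 0 in the Group 3 line and 2 for the difference.

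Against a 1.5-fold change glmTreat called 1279 genes for T3 in cohort 1, 1579 for T3 in cohort 2, 1656 for GSK126, 1 for T3 against GSK126, 38 in the SHH line, 3 in the Group 3 line and 2 for the difference, as a stricter hypothesis must. DESeq2 called 137 for T3 against GSK126, 669 in the SHH line, 96 in the Group 3 line and 178 for the difference. Without a filter on low counts 17 were called for T3 against GSK126 and 60 in the Group 3 line. Only the compared groups in the fit gave 1 for T3 against GSK126. Both PDOX lines in a joint fit gave 123 in the SHH line and 120 in the Group 3 line, since a joint fit gives them a common spread. Without PBS 1 and T3 3 the Group 3 line gave 377.

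Camera with an estimated correlation called 0 lists in each single comparison (9, 8, 8, 3, 3 and 4 at the preset one) and 1 of 4 for the difference. Fry called 12 for T3 in cohort 1, 15 for T3 in cohort 2, 13 for GSK126, 0 for T3 against GSK126, 8 in the SHH line and 0 in the Group 3 line, and in mixed direction 21 for T3 in cohort 1, 23 for T3 in cohort 2, 21 for GSK126 and 20 in the SHH line. The endothelial list of the SHH line turned from down to up with fry (adjusted p = 0.00211, and 0.0471 with the block). Over genes with a mean log2 CPM of at least 3 the correlation between the mouse cohorts was 0.405 and that between the PDOX lines 0.226.

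With 1 library left out the counts ranged from 2767 to 4685 for T3 in cohort 1, 3734 to 4967 for T3 in cohort 2, 3982 to 5571 for GSK126, 2 to 11 for T3 against GSK126, 776 to 1055 in the SHH line, 1 to 106 in the Group 3 line and 12 to 279 for the difference. Lists called ranged from 9 to 11, 7 to 11, 8 to 11, 4 to 8, 3 to 3, 2 to 4 and 3 to 5 in the same order. The correlation of T3 and GSK126 effects ranged from 0.885 to 0.892. With 2 libraries in a group fewer degrees of freedom remain.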

Other observations

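Tests chosen only after the result was seen are those of the interferon and immediate-early lists and of the PDOX gene sets in mouse cells.

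Immediate-early genes, which respond within minutes to signals and handling, were lower with treatment in mouse cohort 2, and less clearly so in cohort 1. Of 31 such genes 16 fell and none rose with T3 in cohort 1 (median -0.76), 26 fell with T3 in cohort 2 (median -3.14) and 22 fell with GSK126 (median -2.39). By camera with an estimated correlation p was 0.0861, 0.0153 and 0.0219. In cohort 1 the list's median log2 CPM overlapped, at 3.79 to 4.6 over PBS libraries and 3.37 to 4.12 over T3 libraries. Its share of counts was 0.145% with PBS and 0.102% with T3 there. In cohort 2 that share was 1.51% with PBS, whose libraries stood apart, 0.105% with T3 and 0.113% with GSK126. In the SHH line 2 of 28 rose and none fell (median -0.06), and in the Group 3 line none of 22 was called by edgeR.

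Interferon-stimulated genes also rose with GSK126 in cohort 2 (25 of 29, none fell, median 3.21, and p = 0.17 with an estimated correlation). They took 0.0125% of counts with PBS, 0.0646% with T3 and 0.077% with GSK126 there, and in cohort 1 0.788% with PBS (SD 0.402) and 0.126% with T3 (SD 0.0612). In the SHH line 1 of 18 rose.

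A hypothesis was that cohort 2 and the SHH line share part of the T3 response, seen against GSK126. The 589 mouse counterparts of genes that rose in the SHH line were higher with T3 than with GSK126 (60.3% above 0, median 0.08, camera p = 0.00044, and 0.0116 with an estimated correlation), and the 444 counterparts of genes that fell were lower (34.9% above 0, median -0.10, p = 0.00455, and 0.0308). Against PBS the same sets gave p = 0.149 and 0.57 with an estimated correlation, so the hypothesis did not hold there, and with GSK126 against PBS they gave 0.958 and 0.104. With T3 in cohort 1 the medians pointed the opposite way, at -0.08 (43.4% above 0, p = 0.408 with an estimated correlation) for the first set and 0.12 (57.3% above 0, p = 0.47) for the second. Group 3 sets gave 0.778 and 0.312 for T3 against GSK126. Of 4 genes called there and tested in the SHH line, Syt12 (2.75 and 2.90), Sema3c and Actn1 moved alike. Medians were small.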
